A study of Camellia sinensis with 4 samples.

How the data were processed

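RNA from tea leaves (Camellia sinensis) was measured on 4 one-colour Agilent arrays that lay on 1 slide. The groups were blister blight control, blister blight infected, grey blight control and grey blight infected, with 1 array in each. Per the labels' protocols, RNA was extracted with a column kit, primed with oligo-dT, amplified with T7 polymerase and labelled with Cy3. The labels speak of plants kept in 3 replicates, and whether RNA of several plants was pooled on an array is not stated.

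The deposited files hold each array's spot intensities. Per the file headers, they were made with Agilent Feature Extraction 10.7.3.1, and the processed intensity is background-subtracted and detrended within the array, with surrogate values for spots near background, and is not scaled between arrays. The deposited value table holds log2 values made by the authors, and no label or header records how. Set against the log2 processed intensity of the same array, each column of that table correlated at 0.988 to 0.99 and differed by a near-constant offset. After removing that offset, 98.8% of probes on each array lay within 0.05. Its column medians were -0.56, -0.75, -0.64 and -0.93 in the order of the groups above, and each column's 75th percentile was -0.01. Its scale is thus log2 and it is centred near the 75th percentile of all probes of an array. How spots of a probe were combined there stays unknown.

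The array carries 28188 non-control probes on 43803 spots, each a 60-base sequence. Of these, 610 are tea sequences, 27564 are Arabidopsis thaliana sequences and 14 carry other descriptions, among them patent entries. Probes for 490 tea sequences, 219 Arabidopsis sequences and some of those with other descriptions are spotted 22 or 23 times, and the others once. An Arabidopsis probe reports whatever transcript in the leaf RNA hybridises to it, so its gene name is that of the probe sequence. The other 120 tea probes carry a mark for cross-hybridisation in their probe names and are on 1 spot each, so their values are uncertain between near-identical sequences. Among the genes named these are the thaumatin-like protein, CsRIP3, the RD22-like protein, the putative dehydrin FJ014474.1, the metallothionein-like protein and caffeine synthase 1. Gene names were those of the scanner files, since 0 of the probes' accessions matched the gene table provided for assembly GCF_055761805.1, and no genome position is given.

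Spots marked by the software as non-uniform or as population outliers were left out, which removed 1.96% to 2.78% of spots per array. The log2 processed intensities of a probe's spots were averaged. A probe counted as above background where over 50% of its spots were marked well above background. This held for 2818, 3194, 3085 and 3423 probes on the 4 arrays, or 10.0% to 12.1% of them, and for 1457 probes on all 4. Since under 50% of the probes were detected, each array was scaled by subtracting the 75th percentile over those 1457 probes. The plan written before the data were examined had named the 75th percentile over all probes. That percentile lay at an intensity of 2.98 to 4.13, below the lowest detected intensity of any array, which was 7.1. The planned wording was therefore kept as an alternative, and its counts stand beside the main ones. A probe saturated on both arrays of a pair was left out, which concerned 11 probes for blister blight, 12 for grey blight and 23 for the controls. For a probe saturated on 1 array, its difference is a bound.

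Within a disease, 1 array per group leaves no residual degrees of freedom, so no test was made there. A fit of infection over both diseases, with disease as a block, would leave 1, and it was not run because the diseases differ in pathogen and clone. No p-value is given. The number of arrays limits the precision. Differences are log2 infected minus log2 control, over probes above background on both arrays of a pair. Counts were taken at 2-fold. The standard error over spots, given for some probes, covers spot-to-spot error within an array only. The median SD between spots of a detected probe was 0.064 to 0.07 on the log2 scale. For a probe above background on 1 array of a pair, the fold is a lower bound, taken as its scaled level there against the higher of its own level and the lowest detected level on the other array.

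A set of 24 gene lists was fixed as text patterns on the annotation before the data were examined. For each list with at least 5 measured members, the median difference was set against 10000 random lists of the same size matched on level in 20 bins. Because scaling moves the median of all probes, list medians and the numbers of list members above or below are given relative to the median of all measured probes of the pair. The named genes follow a rule fixed before the data were examined. It takes the 8 named probes with the largest difference in each direction of each disease, the 2 members of each list with the largest absolute difference, up to 3 per direction among probes above background on 1 array, and, across the diseases, the 4 highest in both, the 4 lowest in both and the 4 in each opposite direction. It takes 1 probe per annotation text, and fewer of the list and one-array genes are printed for length.

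The alternatives were scaling on the median of detected probes, quantile normalization, normexp background correction (offset 50) with quantile normalization, scaling on 6 spike-in probes, the deposited log2 values, no filter and a stricter filter on dim probes, saturated spots left out, thresholds of 1.5-fold and 4-fold, 1 value per gene name, and, for the lists, means or 1 value per annotation text. The all-probe percentile, a lowess correction (span 0.3) of the difference on level, tea probes alone, replicated probes alone, random lists also matched on the species of the probe and the ribosomal list without organelle members were added after the data had been seen. The calculation was tested on simulated pairs made from each control array with 200 changed probes. Among 2818 probes simulated from the blister blight control, 95.0% of probes changed by 1.5 on the log2 scale and 100.0% of those changed by 2.5 were called, with 3 of 2618 unchanged probes. Among 3085 simulated from the grey blight control, these shares were 97.0% and 100.0%, with 0 of 2885 unchanged probes. The simulation holds spot error and no variation between plants. It gave both arrays of a pair the control's background marks, so no lowered probe could drop out. As many probes were raised as lowered, so an uneven split, which could affect the scaling, was not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.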

Results

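Whole tea leaves infected with 1 of 2 leaf pathogens were compared with control leaves. Blister blight is caused by Exobasidium vexans and was studied in the tea clone SA-6. Grey blight is caused by Pestalotiopsis theae and was studied in the clone UPASI-10. Each of the 4 groups had 1 array, so no difference below has a replicate check, and array position on the slide cannot be told apart from group. Between 77.0% and 79.7% of the 610 tea probes and between 8.42% and 10.6% of the 27564 Arabidopsis probes were above background on an array. The array has no probe of either fungus, and the 12 probes matched by the list for fungal transcripts were all Arabidopsis sequences. Fungal RNA was therefore not measured by probes of its own, and any that hybridised to other probes cannot be told apart.

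The first comparison asked which leaf transcripts differed between blister blight infected and control leaves. Some defence proteins and some members of the jasmonate list were among the highest transcripts in the infected leaf. Thaumatin-like protein (DQ444296.1), a pathogenesis-related protein, was 5.81 higher on the log2 scale, a 56.0-fold difference, from 1 spot with a near-identical partner sequence. Chitinase chit1b (GQ902047.1), which cleaves the chitin of fungal walls, was 5.31 higher (spot standard error 0.019), or 39.6-fold. Allene oxide synthase aos1 (FJ872021.1) was 3.73 higher and lipoxygenase lox1 (EU195885.2) 3.25 higher, and both belong to the list for jasmonate synthesis and signalling. The lowest transcripts were a putative tea geometrid larvae-inducible protein (FJ943231.1) at -9.88 and the putative cold-inducible protein Cs044 (EU563236.2) at -9.76.

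Other transcripts high in the blister blight infected leaf were a glucose-6-phosphate/phosphate translocator (FJ648829.2) at 3.70 and 3-hydroxy-3-methylglutaryl-CoA synthase (JQ390224.1), an enzyme of the mevalonate pathway, at 3.53. The Arabidopsis probes for the potassium channel KCO5 and the tubulin TUA2, each on 1 spot, stood at 4.56 and 3.38. The log2 signal of KCO5 on the control array, 3.82, lay near the lowest detected level there. At the low end, flavone synthase II (FJ169499.1) stood at -4.71, the ribosome-inactivating protein CsRIP3 (GU951537.1) at -4.55 and a gibberellin induced protein (HM003241.1) at -3.70. A beta-1,3-glucanase (AF399920.2), which cleaves callose and fungal glucans, was lower by the same measure at -3.89. The Arabidopsis probes for the auxin-responsive AT4G34760 and for MLP328 stood at -4.41 and -3.67.

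Among the fixed lists, jasmonate synthesis and signalling was higher than other probes in blister blight. Its 8 measured members had a median 1.26 above that of all measured probes, at percentile 99.97 of matched random lists, and 5 of them lay at least 2-fold above and 0 at least 2-fold below. Among members chosen after their values were seen, lipoxygenases lox3 (FJ794853.1) and lox4 (HM370508.1) stood at 3.17 and 1.28 and lox2 (FJ418174.1) at 0.16, which turned negative with spike-in scaling. Redox and detoxification enzymes had a median 0.72 above the rest over 18 members, higher than all the random lists, with glutathione peroxidases HM003262.1 and JQ247186.1 at 2.30 and 1.95. Ubiquitin and proteasome genes had a median 0.35 above the rest over 71 members, at percentile 99.98, with 11 members above and 6 below by 2-fold.

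Light-reaction and cell division transcripts were lower than other probes in the blister blight infected leaf. The 23 light-reaction members had a median -0.68 relative to all probes, at percentile 0.03, with 10 at least 2-fold below and 1 above. They included the Arabidopsis probe for the chlorophyll-binding protein CAB3 at -2.03 and a tea chlorophyll a-b binding protein (HM003376.1), saturated on the control array, at -1.97. The 42 members of cell division and histones had a median -0.73, below all random lists, with 15 at least 2-fold below and 2 above. A tea cyclin (JF795471.1) stood at -2.81 and cyclin B (AB247280.1) at -2.67. Plastid-encoded genes had a median -0.42 at percentile 1.40, cell wall remodelling -0.27 at percentile 1.97 and flavonoid and catechin synthesis -0.20 at percentile 2.03. The plastid and flavonoid lists fell inside the middle 95% when random lists were also matched on the species of the probe, at percentiles 4.73 and 3.46. The flavonoid list did so too with 1 value per annotation text, at percentile 2.56, and its median turned positive, to 0.0263, without a filter on dim probes. Anthocyanidin synthase (AY830416.1) and flavonoid 3',5'-hydroxylase (AY945842.1) stood at -2.58 and -1.98.

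Chitinase chit1b and the thaumatin-like protein belong to the list of pathogenesis-related proteins, as do the beta-1,3-glucanase at -3.89 and MLP328 at -3.67. That list held members on both sides in blister blight. Its 26 members had a relative median of -0.10 at percentile 34.40, with 3 above and 5 below by 2-fold. That median was 0.54 with the stricter filter on dim probes, 0.51 with tea probes alone and -1.72 with replicated probes alone, so its direction rests on which probes are counted. Transcription factors linked to stress had a relative median of -0.01 over 29 members, with the tea factor NAC1 (JN857066.1) at 3.39 and the Arabidopsis probe WRKY25 at 2.39. Heat shock proteins had a relative median of 0.07 at percentile 50.28, with HSP70 (AY694190.1) at 2.68 and a DnaJ protein (DQ345453.2) at 2.57. Both measured ethylene genes were higher, ACC oxidase (DQ904328.1) at 1.55, with 1 array saturated, and ACC synthase (EF205149.1) at 1.29. The members measured for the salicylate list were the pectin methylesterase PMEPCRF at -2.56 and a methylesterase inhibitor (AT1G62770) at -2.26, which act on cell wall pectin. Of the other lists, phenylpropanoid and lignin synthesis stood at 0.29, caffeine and theanine metabolism at 0.29, dehydration and osmotic proteins at 0.50, receptors and resistance proteins at -0.23, ribosomal proteins at -0.03, reference genes at -0.02 and carbon fixation near 0, all inside the middle 95% of random lists. Without its 12 organelle members the ribosomal list stood at 0.11. In all, 8 of 18 lists lay outside that range in blister blight and 7 of 18 in grey blight, where chance alone gives 0.9. Between the control arrays, with no infection, 6 of 19 lists did, where chance alone gives 0.95.

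The sizes of these list medians moved with the processing. With normexp and quantile normalization the relative medians were 0.11 for ubiquitin and proteasome genes, 0.36 for redox enzymes, -0.06 for cell wall remodelling and -0.30 for flavonoid synthesis. With quantile normalization alone, cell wall remodelling stood at -0.14 and flavonoid synthesis at -0.39, and with the stricter filter cell wall remodelling stood at -0.52. Without a filter on dim probes, the relative medians of the 8 lists outside the random range lay between -0.09 and 0.03. With tea probes alone, jasmonate synthesis stood at 3.1. With replicated probes alone, it stood at 3.08, redox enzymes at 1.17, light reactions at -1.06 and flavonoid synthesis at -0.47. As means, the plastid list stood at -0.27, the flavonoid list at -0.42 and the dehydration list at -0.30, and caffeine and theanine metabolism stood at -0.86 with replicated probes alone. With the stricter filter, receptors and resistance proteins stood at -0.50 and reference genes at 0.25.

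In all, 181 of 1792 probes measured in blister blight were at least 2-fold higher and 202 at least 2-fold lower, of which 62 and 69 were tea probes. Higher probes made up 47.3% of these, and 21.8% when arrays were scaled on the spike-ins. The all-probe percentile gave 212 and 174. Between the control arrays, which differ in clone, plant and array position, 113 of 1778 probes were at least 2-fold higher and 195 at least 2-fold lower in the grey blight control. Higher probes made up 36.7% of these, and 46.5% with normexp and quantile normalization. The share was 57.1% with scaling on the median, 57.8% with quantile normalization, 67.8% with the deposited values, 68.4% with the all-probe percentile and 83.0% with spike-in scaling.

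The second comparison asked the same of grey blight. Some defence and jasmonate transcripts and ACC synthase were among the highest in the infected leaf. Allene oxide synthase aos1 was 9.25 higher (spot standard error 0.046), lipoxygenase lox1 5.81 higher, the thaumatin-like protein 7.57 higher and chitinase chit1b 6.83 higher. ACC synthase, which makes the precursor of ethylene, was 6.62 higher, and the transcription factors MYB (GU944769.1) and WRKY40 (JQ820201.1) were 6.94 and 6.03 higher. In the grey control relative to the blister control, ACC synthase stood at -3.16 and WRKY40 at -1.23. The thaumatin-like protein and chitinase chit1b stood at 1.59 and 1.36 in that comparison of controls. ACC oxidase (DQ904328.1), the other measured ethylene gene, stood at 0.72, and at -0.17 with the all-probe percentile, -0.16 with the deposited values and -1.18 with spike-in scaling. The geometrid larvae-inducible protein at -10.73, the gibberellin induced protein at -8.22 and flavone synthase II at -5.89 were the lowest.

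The glucose-6-phosphate/phosphate translocator stood at 7.60 in grey blight. Other transcripts at the low end were a basic blue protein (HM003271.1) at -5.71 and an RD22-like protein (FJ648830.1) at -4.87, both saturated on the control array so that each was lower by at least that much. Flavonoid 3',5'-hydroxylase stood at -4.82, AT4G34760 at -4.40 and CAB3 at -4.39. The beta-1,3-glucanase was above background in the grey blight control and not in the infected leaf, a difference of at least 40.0-fold. A patented drought-tolerance sequence of tea (DL205660.1), spotted 23 times, was at least 186.3-fold higher in the infected leaf, and it was at least 28.1-fold higher in blister blight.

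Dehydration and osmotic proteins stood highest among the lists with at least 5 measured members in grey blight. All 8 members were tea probes, their median lay 1.90 above that of all probes at percentile 99.98, and 5 of them lay at least 2-fold above. Dehydrin 1 (JN400597.1) stood at 4.68 and a putative dehydrin (FJ014474.1) at 3.79. In the grey control relative to the blister control, these dehydrins stood at -2.61 and -1.17. Heat shock proteins and chaperones had a median 0.90 above the rest over 18 members at percentile 99.91, with 7 above and 1 below by 2-fold. The DnaJ protein stood at 4.91 and HSP70 at 3.80. Phenylpropanoid and lignin synthesis had a relative median of 0.61 at percentile 97.13, inside the middle 95% of random lists, with cinnamyl alcohol dehydrogenase (HQ880207.1) at 3.41 and a hydroxycinnamoyltransferase (JQ619537.1) at -4.36.

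Light-reaction, flavonoid and cell division transcripts were lower than other probes in grey blight. The 21 light-reaction members had a median -2.08 relative to all probes, where the middle 95% of random lists spanned -0.73 to 0.45, and 14 lay at least 2-fold below and 1 above. Flavonoid and catechin synthesis had a relative median of -1.75 over 24 members at percentile 0.01, with 14 below and 0 above by 2-fold. Flavonoid 3',5'-hydroxylase and a putative isoflavone reductase (AT4G39230), at -4.82 and -4.19, had the largest differences of the list. They were 0.76 and 2.83 higher in the grey than in the blister control, and AT4G39230 stood at 0.84 in blister blight. Cell division and histones had a relative median of -1.45 over 43 members, with 29 below and 2 above by 2-fold and cyclin D3-1 (AB247282.1) at -2.75. That cyclin was 1.24 higher in the grey than in the blister control. Plastid-encoded genes stood at -1.56 and cytosolic ribosomal proteins at -0.64, at percentiles 0.16 and 0.08, and the control arrays differed in the ribosomal list too, by 0.57. The ribosomal pattern also took in organelle members, which the values of this list include. Without these 13 the relative median was -0.48, and no percentile was taken. Not counted relative to the median, 6 members were then at least 2-fold lower and 5 higher, against 14 and 6 with them.

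Pathogenesis-related proteins had a relative median of 0.47 over 29 members at percentile 93.14 in grey blight, with 8 above and 3 below by 2-fold. That median was 4.51 with its 5 tea probes alone and 1.2 with the stricter filter. The beta-1,3-glucanase, at least 40.0-fold lower, was below background in the infected leaf, so it is not counted in these medians. Jasmonate synthesis had a relative median of 0.56 over 7 members at percentile 92.44, with lox3 at -0.11 and the Arabidopsis probe AOS, also chosen after its value was seen, at 1.19, and below 0 with spike-in scaling. Receptors and resistance proteins stood at 0.35, stress-linked transcription factors at 0.20, redox enzymes at 0.20 and ubiquitin and proteasome genes at 0.21, each inside the middle 95% of random lists. Carbon fixation stood at -1.11 at percentile 2.59, with the small subunit of Rubisco (AT5G38430) at -3.74. Caffeine and theanine metabolism stood at -0.45, and at -1.36 (percentile 5.0) with 1 value per annotation text, cell wall remodelling at 0.14 and reference genes at -0.09. Phenol oxidation had 0 members above background on both arrays of a pair, and the lists for senescence and for sugar transport had 4 measured members each in either pair. A metallothionein-like protein (HM003273.1) of the senescence list stood at 1.32 in blister and 3.93 in grey blight.

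The list medians of grey blight moved with the processing as well. With normexp and quantile normalization the relative medians were 0.32 for heat shock proteins, -0.96 for flavonoid synthesis, -0.76 for cell division and -0.21 for ribosomal proteins. Ribosomal proteins stood at -0.40 with quantile normalization alone and at -0.39 with the level trend removed. Without a filter on dim probes, the relative medians of the dehydration, heat shock, light-reaction, flavonoid, cell division and ribosomal lists lay between -0.11 and 0.16, and carbon fixation stood at 0.02. With tea probes alone, heat shock proteins stood at 3.04, light reactions at -1.35 and flavonoid synthesis at -0.76. Redox enzymes stood at 0.62 with quantile normalization and at 0.65 with the level trend removed (percentile 97.40), and stress-linked transcription factors at 0.80 as a mean. Receptors and resistance proteins stood at 0.07 with normexp and quantile normalization and at 0.94 with replicated probes alone, and phenylpropanoid synthesis at 1.36 with replicated probes alone. Caffeine and theanine metabolism stood at -0.92 without a filter, -1.01 with tea probes alone and -0.94 as a mean. The dehydration list stood at 1.11 with saturated spots left out, the flavonoid list at -1.07 with the stricter filter and the plastid list at -0.95 as a mean.

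**Figure D1:**
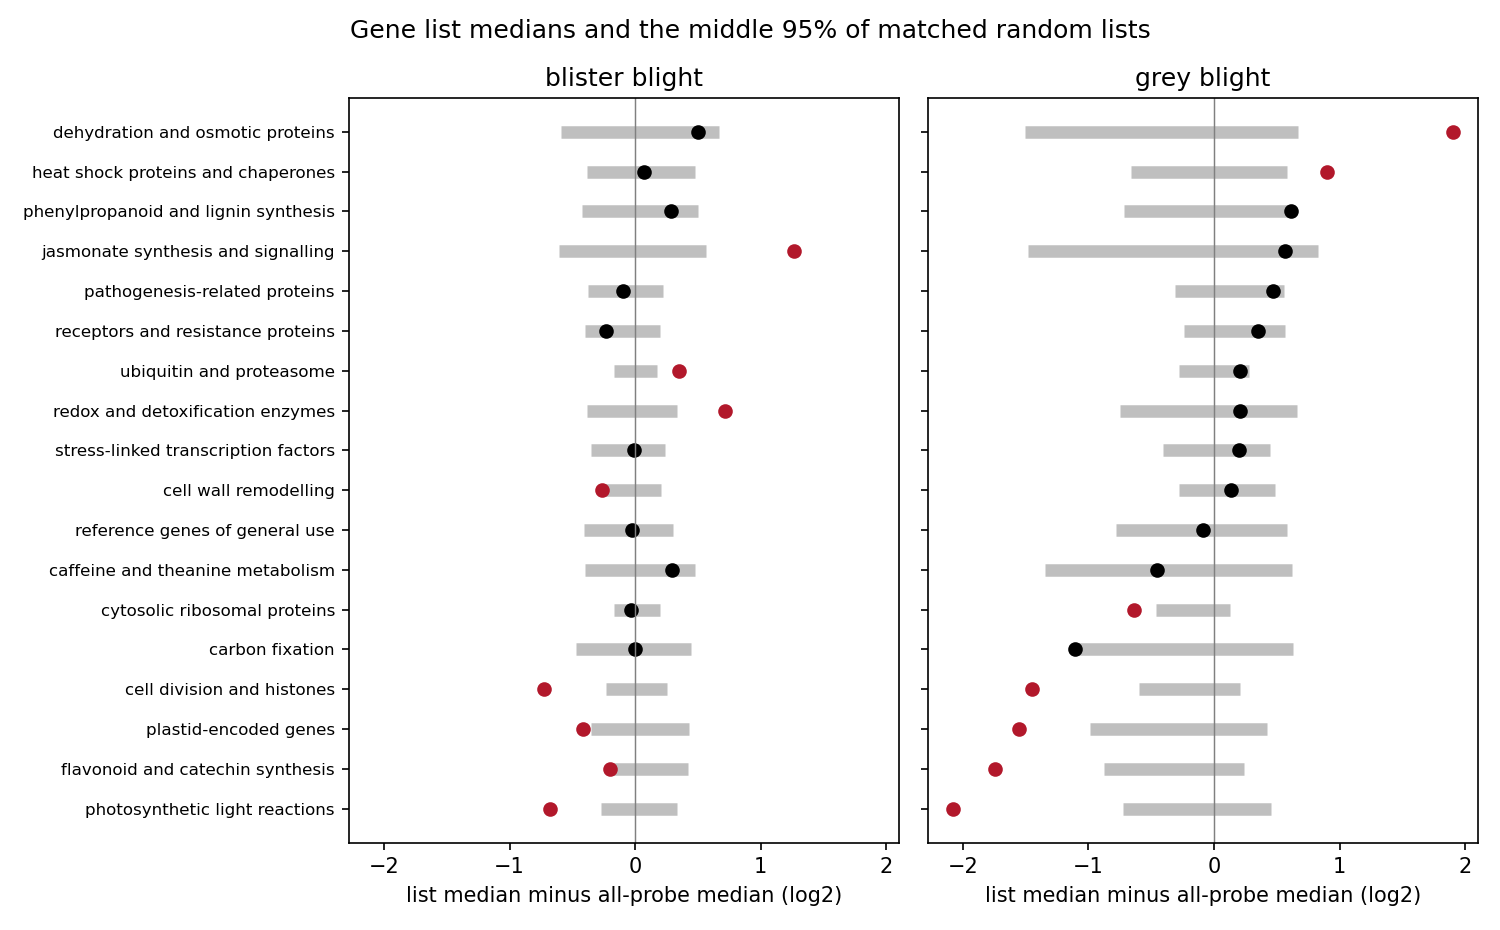
Dots give the median log2 difference (infected minus control) of each gene list minus the median of all measured probes, in blister blight (left) and grey blight (right), and grey bars give the middle 95% of 10000 random lists matched on level. Red dots lie outside their bar, and the light-reaction list stands at -0.68 and -2.08.

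In grey blight, 534 of 1820 measured probes were at least 2-fold higher and 251 at least 2-fold lower, and tea probes were split 112 and 112. The split rests on the scaling. Higher probes made up 68.0% of these, but 54.8% with scaling on the median, 44.9% with quantile normalization, 48.5% with normexp and quantile normalization, 23.9% with the deposited values, 23.8% with the all-probe percentile (172 higher and 550 lower) and 4.8% with scaling on spike-ins. The median difference over all measured probes was 0.43 in the main scaling, -0.46 with the all-probe percentile and -1.47 with spike-in scaling. Counted relative to that median, 281 probes lay at least 2-fold above and 360 at least 2-fold below.

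**Figure D2:**
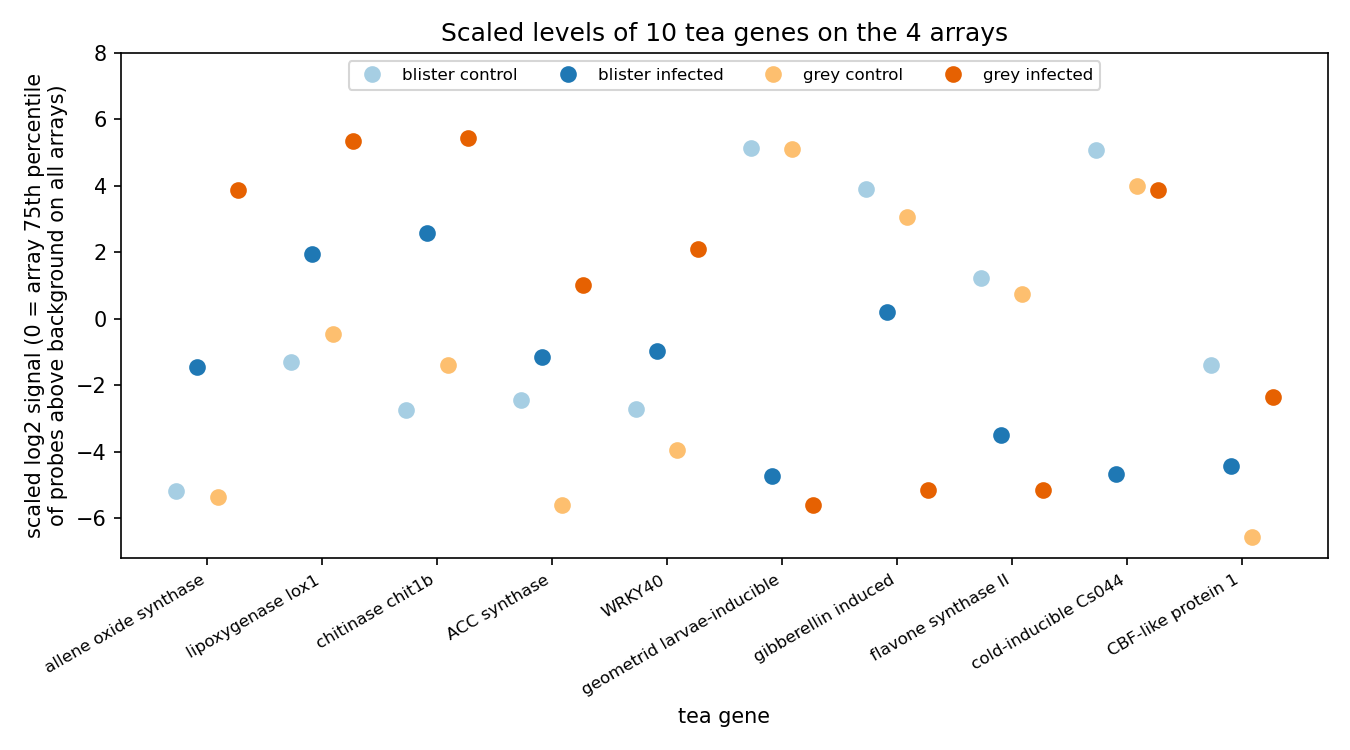
Scaled log2 intensity of 10 tea genes on each of the 4 arrays, with 1 dot per array and 0 at the array's 75th percentile of probes above background on all arrays. Allene oxide synthase stood 3.73 and 9.25 higher in the infected leaves, and the geometrid larvae-inducible protein -9.88 and -10.73 relative to the controls.

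The third comparison set the diseases side by side, and their contrasts share no array. Transcripts that were high or low in one disease tended to be so in the other. The thaumatin-like protein, chitinase chit1b, allene oxide synthase and the glucose-6-phosphate/phosphate translocator were the 4 highest named genes in both, and the geometrid larvae-inducible protein, flavone synthase II, AT4G34760 and the gibberellin induced protein the 4 lowest in both. A CBF-like protein 1 (EU563238.1), a transcription factor family of the cold response, stood at -3.04 in blister and 4.20 in grey blight, and the putative dehydrin at -2.03 and 3.79. The tubulin probes TUA2 and TUB7 stood at 3.38 and 2.09 in blister and at -1.56 and -1.45 in grey blight, whereas tea alpha tubulin 1 (DQ340766.2) stood at -2.56 and -1.64, a gene chosen after its values were seen. The grey value of TUA2 comes from 1 spot near the lowest detected level of the infected array.

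A thiazole biosynthetic protein (JF288557.1) stood at 1.28 in blister and -2.43 in grey blight, and caffeine synthase 1 (AY570929.1) at 0.99 and -1.01. The probes UNE14 and AT1G60250 stood at -1.30 and -1.73 in blister and at 1.40 and 1.29 in grey blight, and the grey values of both turned negative with spike-in scaling. Cold-inducible Cs044 stood at -9.76 in blister and at -0.12 in grey blight, where it stood at -1.02 with the all-probe percentile.

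Across the 1440 probes measured on all 4 arrays, the log2 differences of the diseases had a Pearson correlation of 0.53 and a Spearman correlation of 0.41. For tea probes these were 0.63 and 0.58, and for Arabidopsis probes 0.41 and 0.33. Probes are not independent replicates. At least 2-fold higher in both were 90 probes, where lists drawn independently would share 42.5, and at least 2-fold lower in both were 77, against 22.2. In opposite directions were 27 probes, against 63.9, of which 24 were lower in blister and higher in grey blight. In the main scaling 408 of the 1440 probes were higher and 222 lower in grey blight, so this split may rest in part on the scaling. With scaling on the median, 14 probes were opposite. Spike-in scaling gave 20 higher and 234 lower in both. Without a filter on dim probes, where most probes were below background, the Pearson correlation was 0.07 and 976 probes were opposite.

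In the difference between the diseases, 3 lists stood above random lists and 4 below. Each disease was studied in a clone of its own, so disease and clone cannot be told apart in any of these differences. Each difference also takes in the 2 control arrays, so a list lower in the grey control is raised in it and a higher one lowered. Dehydration and osmotic proteins were higher in grey than in blister blight by 2.64 relative to all probes, above all random lists. This list stood at -0.41 in the grey control relative to the blister control, which adds to its difference. Heat shock proteins were higher by 0.88 and receptors and resistance proteins by 0.82, at percentiles 99.55 and 98.40. The receptor list lay inside the random range in each disease, and these random lists were not matched on species. Flavonoid and catechin synthesis stood at -1.32, caffeine and theanine metabolism at -1.22, light reactions at -0.91 and ribosomal proteins at -0.63, at percentiles 0.01, 1.08, 1.60 and 0.33. The flavonoid, caffeine and ribosomal lists were higher in the grey than in the blister control, by 0.53, 0.70 and 0.57, which lowers their differences between the diseases.

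**Figure D3:**
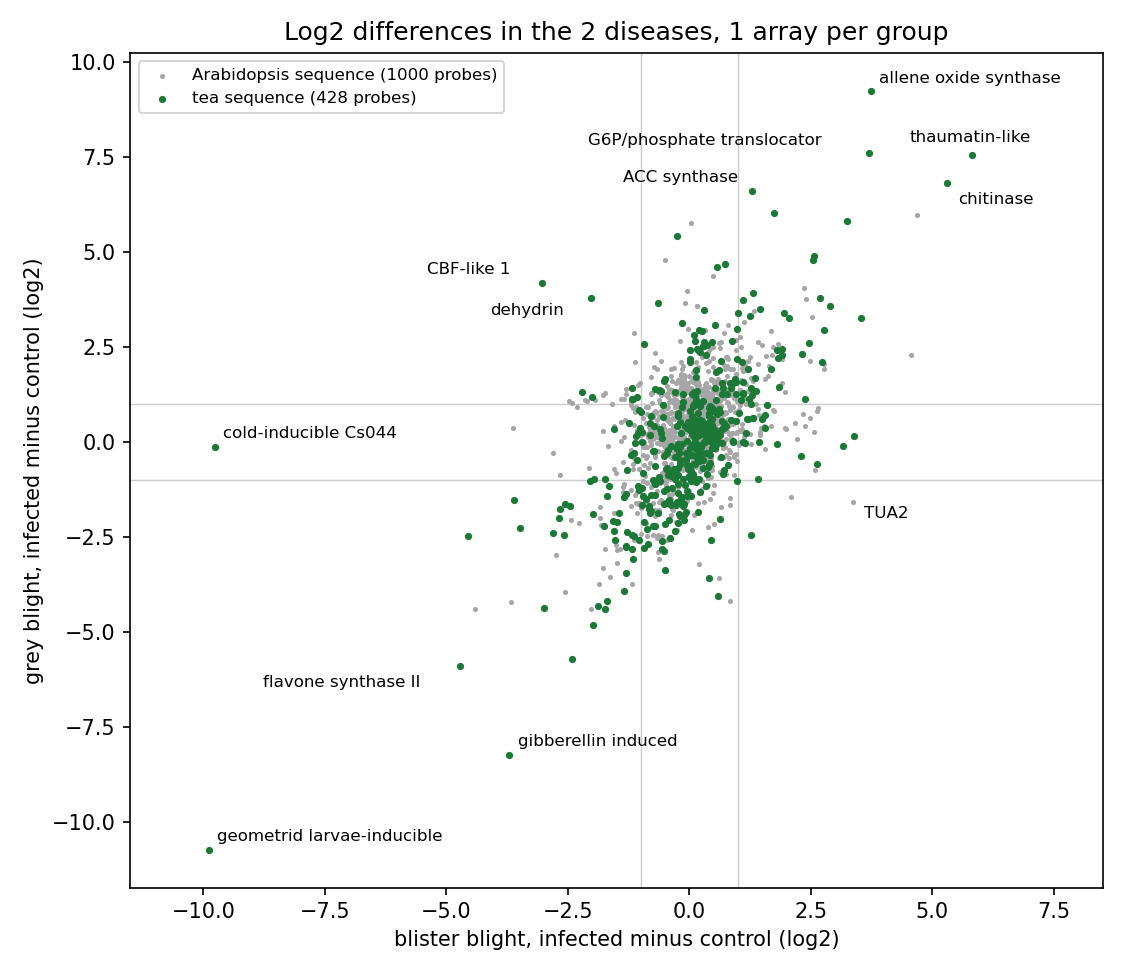
Each dot is 1 tea or Arabidopsis probe above background on all 4 arrays, at its log2 difference (infected minus control) in blister blight on the horizontal and in grey blight on the vertical axis, with tea sequences in green and Arabidopsis sequences in grey. Lines mark 2-fold, and the Pearson correlation was 0.53 across 1440 probes, of which those with other descriptions are not drawn.

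Some probes were above background on 1 array of a pair. In blister blight 1391 were so in the infected leaf alone and 1015 in the control alone, and in grey blight 1591 and 1253. Of these, 10 and 13 in blister blight and 25 and 14 in grey blight were tea probes. A cold-inducible GRP gene (GQ461357.1) was at least 54.0-fold lower in the blister blight infected leaf. MYB was at least 11.5-fold higher there, and a dehydrin gene (FJ436979.1) at least 22.5-fold higher in grey blight. The last of these was chosen after its value was seen. An Arabidopsis probe for anthranilate synthase (AT3G55870), an enzyme of tryptophan synthesis, was at least 51.7-fold lower in blister and at least 61.3-fold lower in grey blight.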

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

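The tests on spike-in brightness were chosen after those values had been seen, as were the extra ratios given for single-array calls. Spike-in spots, which the main comparisons did not use and 1 alternative scaling did, were brighter on the infected array of both pairs, with a median log2 difference of 0.24 in blister and 0.60 in grey blight. Leaf probes went the other way. Before scaling, of the 1457 probes detected on all arrays 57.2% were dimmer on the infected array in blister blight (median -0.09, a gap of 0.32 to the spike-ins) and 81.2% in grey blight (median -0.96). In grey blight, a weaker hybridization or scan of the whole array would dim the spike-ins as well, and their 6 differences lay between 0.45 and 0.71 with a median of 0.60, which argues against it. The gap of 1.56 between spike-ins and leaf probes, which partly restates the pattern, is what a smaller share of labelled leaf cRNA beside the spike-ins would give, and it may come from less tea mRNA in the infected leaf, from fungal mRNA labelled along with it, or from more spike-in mix in that tube. These stay open, since the amount added is not recorded and no fungal probe is on the array. Part of the gap may lie in the control array. The grey control had a 75th percentile of 1341.1 over the probes detected on all arrays, against 879.7 in the blister control. Their mean log2 spike-in signals were 10.465 and 10.459, and these controls also differ in clone.

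Several genes stood out because their difference had opposite signs in the diseases. With 1 array per group, the differences between the diseases were not tested, and disease cannot be told apart from clone. Grey minus blister was 7.24 for CBF-like protein 1 (EU563238.1), 5.82 for the putative dehydrin (FJ014474.1), 3.02 for AT1G60250 and 2.70 for UNE14. It was -4.94 for TUA2, -3.54 for TUB7 and -3.71 for the thiazole biosynthetic protein (JF288557.1). TUA2 is on 1 spot, and its log2 signal of 2.94 on the grey infected array lay near the lowest detected level there. The difference between the diseases also holds that between the controls, with its sign reversed. A gene lower in the grey than in the blister control is raised by it, and a higher one lowered. In the grey control relative to the blister control, CBF-like protein 1 stood at -5.16, AT1G60250 at -2.30, UNE14 at -1.91, the putative dehydrin at -1.17, TUB7 at 1.37, the thiazole biosynthetic protein at 1.02 and TUA2 at 0.27.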

How the results depend on the processing

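The all-probe percentile, the removal of a level trend, tea probes alone, replicated probes alone and species-matched random lists were added after the data had been seen. Of the alternative values of the counts and the correlation, 64 stayed within 1.5 times the main count or within the bootstrap SD of the correlation (0.038) and 73 did not. Of the list medians 419 moved by less than the spread of their members and 65 by more, besides 1 that lay outside its random range and changed sign. Lists inside the range included, 32 values of 12 list medians changed sign. Scaling on the median, on spike-ins or on the all-probe percentile shifts a whole array and cannot move the relative list medians or the correlation. The deposited values differ by a near-constant offset and can hardly move them. The list and correlation values under these settings stayed by construction. Of the named genes' values 67 were counted as the same against spot error and 618 as moved, besides 5 of genes at least 2-fold apart that changed sign. Named genes on 1 spot have no spot error of their own, so this split says little for them. Smaller differences included, 8 values changed sign, and the other 3 were of ACC oxidase (DQ904328.1) in grey blight. The filters and the removal of saturated spots were not run for single named genes. Signal over background limits the Arabidopsis probes most. A fit of infection over both diseases, with disease as a block, was not run. The difference between the diseases in each list was not recomputed under the alternatives. The cause was not tested for the values below, except that thresholds, filters and subsets change counts by construction.

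At 1.5-fold, blister blight had 359 probes higher and 395 lower, grey blight 816 higher, the controls 698 apart, and the diseases shared 193 higher and 145 lower with 86 opposite. At 4-fold, these were 47 and 44 in blister blight, 151 and 95 in grey blight, 68 in the controls, and 22, 17 and 2 across the diseases. Without a filter on dim probes, blister blight had 2327 higher and 2998 lower, grey blight 5649 and 1729 and the controls 5237 apart. The correlation was then 0.0702, with 772 higher in both, 416 lower in both and 976 opposite, and the flavonoid list in blister blight stood at 0.0263 against -0.20. The stricter filter gave 115 and 121 in blister blight, 263 higher in grey blight, 158 in the controls and 14 opposite.

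Scaling on the median gave 14 opposite, and quantile normalization 290 higher in grey blight. Normexp with quantile normalization gave 83 and 79 in blister blight, 160 higher in grey blight, 99 in the controls, a correlation of 0.5936, 44 higher and 48 lower in both and 9 opposite. Spike-in scaling gave 105 and 377 in blister blight, 61 and 1214 in grey blight, and 20 higher and 234 lower in both. In grey blight it turned SHS1 to -0.8326, ACT2 to -0.5419, AT3G02840 to -0.8625, UNE14 to -0.5018 and AT1G60250 to -0.6095. The deposited values gave 173 and 550 in grey blight, and the all-probe percentile 172 and 550. Removing the level trend gave 299 higher in grey blight and 16 opposite.

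Tea probes alone gave 62 and 69 in blister blight, 112 and 112 in grey blight, 89 in the controls, a correlation of 0.6256, 41 higher and 42 lower in both and 9 opposite. Replicated probes alone gave 54 and 57 in blister blight, 95 and 89 in grey blight, 74 in the controls, a correlation of 0.6373, 34 higher and 34 lower in both and 6 opposite. With the software's test of signal over background in place of the well-above-background mark, probes above it on 1 array were 3626 (infected) and 3148 (control) in blister and 4364 and 2742 in grey blight.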

Other observations

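The extra ratios for bright spots were chosen after the first ratio had been seen. The tests that removed a level trend or matched species were added after the data had been seen, with their outcomes still unknown. The matching on level already in place largely set the percentiles of the first. Cyclin D3-2 (AB247283.1), chosen after its values were seen, had probes in blister blight at -0.30, -0.39 and -0.23 and in grey blight at -2.34, -2.51 and -2.13, and these probes were 1.53, 1.95 and 1.62 higher in the grey than in the blister control. Among plastid sequences, 3 probes of the atpE region (AJ429661.1) stood at 1.67, 2.99 and 2.66 in grey blight, against the direction of most of that list, the first of them below 0 with spike-in scaling.

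Light-reaction and cell-division probes were lower than other probes in both pairs. A trend of the difference with signal level was removed by lowess, and the highest of the 4 percentiles (2 lists in 2 pairs) was then 0.06. The random lists were already matched on level, so this percentile could hardly change. With the trend removed, the light-reaction medians were -0.63 in blister and -1.69 in grey blight, and those of cell division -0.75 and -1.34. The medians thus stayed low, and such a trend does not account for the pattern. Matching random lists on the species of the probe as well gave 0.02 at most, and 1 value per annotation text, which merges repeated probes of a sequence, gave 0.02 at most. Infection, the plants and the array positions remain open, since each pair holds 1 plant group per array.

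Most probes above background on 1 array of a pair were single-spot Arabidopsis probes, and 697, 893, 833 and 1153 of these were above background on that array and on no other. Their median intensity was 13.0 to 22.4, against 62.4 to 128.5 for probes detected on all arrays. Sporadic bright spots may account for them. Spots of replicated probes that were below background as a probe were themselves called at 5.40% to 7.01%, which predicts 1.945 times the calls observed. Since this is more than was observed, that rate overstates the error, and leaving out outlier spots gave 0.637 times and negative control spots 1.222 times, but only 0.4 and 0.465 times on the infected arrays. Light from a bright neighbouring spot was not the main source, as a neighbour above 10000 was 1.116 times as frequent beside called as beside uncalled probes.

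More probes were above background on the infected than on the control array, 1.133 times as many in blister and 1.11 times in grey blight. Above 1 common intensity of 11.7, the infected arrays held fewer, 0.889 and 0.728 times the control.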
